A study of Danio rerio with 6 samples.

How the data were processed

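RNA from zebrafish embryos of the AB strain at 36 hours post fertilization (hpf) was sequenced from 3 libraries of wild-type siblings and 3 libraries of *dhx38* mutants. *dhx38* encodes a DEAH-box ATPase of the pre-mRNA splicing machinery. The labels call the tissue tail and, in the extraction protocol, trunk, and they do not state the mutation. Per the labels' protocols, RNA was extracted with Trizol and sequenced on an Illumina HiSeq by 2 providers. Which library went to which provider is not stated. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate clutches, so p-values measure only the spread between these libraries.

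The deposited values are a normalized signal per gene, named normalized CPM per the file headers, with 2 decimals. The submitters' processing notes name fastp, STAR, featureCounts and edgeR and the build GRCz11, without versions, roles or order. The normalization factors, the strand setting and the gene filter are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. The larger deposited table held 21769 genes. A shorter deposited table held 956 of them with equal values, by a criterion not given in the sources used here. Gene symbols were used as deposited, and 20433 gene IDs matched the Ensembl name table.

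The deposited signal was a whole multiple of the value of 1 read in each library, within a tolerance of 0.0055 that covers the rounding to 2 decimals. Over all genes the share of whole values was 100% in sibling replicate 1, 99.8% in sibling replicate 2, 99.9% in sibling replicate 3, 99.8% in mutant replicate 1, 99.7% in mutant replicate 2 and 99.7% in mutant replicate 3. This tolerance exceeds 0.1 of the value of 1 read in each of the 6 libraries, and is the larger share of a read in replicates 1 and 2. A total of 19.5 to 37.7 M reads per library was recovered, and a count of 3 reads equalled 0.0776 to 0.164 normalized CPM. Replicate 3 of both groups was the shallower.

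Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), mutant against sibling. All 21769 genes were tested without a filter and adjusted by Benjamini-Hochberg. The threshold was an adjusted p of 0.05. Fold changes are on this scale, which understates the change of low genes. The 30 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 30 lists. A symbol with several gene IDs was represented by the ID of highest mean. Whether the variance should follow a mean trend had not been fixed in advance. The default was taken after counts with and without the trend had been seen.

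The labels give both groups replicate numbers 1 to 3. Deviations from the group means correlated across genes between same-number libraries, with r of 0.45 for number 1, 0.43 for number 2 and 0.57 for number 3, and 6 of 6 libraries correlated best with their own number in the other group. The numbers were therefore taken to pair the libraries. Whether they share an origin or a sequencing batch cannot be told apart, since replicate 3 of both groups was the shallower and the providers are not assigned. The design fixed in advance named no block, so the fit without it stayed the main one and the block an alternative. Counts with the replicate block had been seen before these correlations were computed. The pairing follows from a bound on r that was set beforehand. No replicate pair agreed within sampling noise: the mean chi-square per gene was between 20.8 and 52.1.

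The genes named were chosen by a rule fixed before the data were examined: *dhx38*; the 5 genes with the smallest p in each direction; the 5 called genes with the largest fold change in each direction at or above the median expression; of each list with at least 3 called members, the 2 called members with the smallest p; and 14 marker genes fixed by name. Among genes taken by p or fold change, symbols that are clone or locus placeholders were passed over. Genes named outside the rule are marked as chosen after their values were seen. Of the named genes 1, and of the 30 lists 1, are not reported here.

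Alternatives fixed in advance were a stricter threshold, a minimum fold change, a filter on low values, centring, the replicate block, leaving out each library, and for the list test ranks, the fold change as the statistic, a preset correlation of 0.05 and a pseudocount of 0.1. The estimated correlation and fry were named in the fixed design as tests, and were entered as alternatives only after the data were seen, as was the estimated correlation with the block. Medians within same-number pairs were also added after the data were seen. Alternatives added after seeing the data were a pseudocount of 0.1 for gene counts, a variance trend, the edgeR 4.0.16 quasi-likelihood test on recovered reads (511 genes called) and the 4 libraries of replicates 1 and 2. During exploration, edgeR models with various terms were also compared with the order of the shorter deposited table, and none reproduced that table.

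The tests were tried on simulated libraries of 21769 genes with this depth and spread, but with no effect shared by same-number libraries. The changed genes were drawn from those at or above the median expression, so changes of lower genes were not tried. At 2-fold, 22 of 50 changed genes were called by limma, at 4-fold 50 of 50, at 8-fold 50 of 50 and at 1.5-fold 0 of 50, with 10 calls among 21569 unchanged genes. With edgeR on reads recovered from the simulated values, 2, 35, 50 and 50 of 50 were called at 1.5-, 2-, 4- and 8-fold. Analyses of intron number, gene length and GC content were planned and not run, because no annotation of the build GRCz11 was used here.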

Results

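Gene expression was measured by RNA-seq in tissue labelled tail or trunk from 36 hpf zebrafish embryos. There were 3 libraries of wild-type siblings and 3 libraries labelled *dhx38* mutant. Depth recovered from the values was 34.7, 36.5 and 20.05 M reads in sibling replicates 1, 2 and 3, and 32.1, 37.7 and 19.5 M in mutant replicates 1, 2 and 3. The first principal component carried 51.8% of the variance and placed mutant replicate 1 (-0.931) between the siblings (-32.2, -26.9 and -18.3) and mutant replicates 2 and 3 (41.6 and 36.7). The second, with 29.8%, set replicate 3 of both groups apart from replicates 1 and 2.

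**Figure D1:**
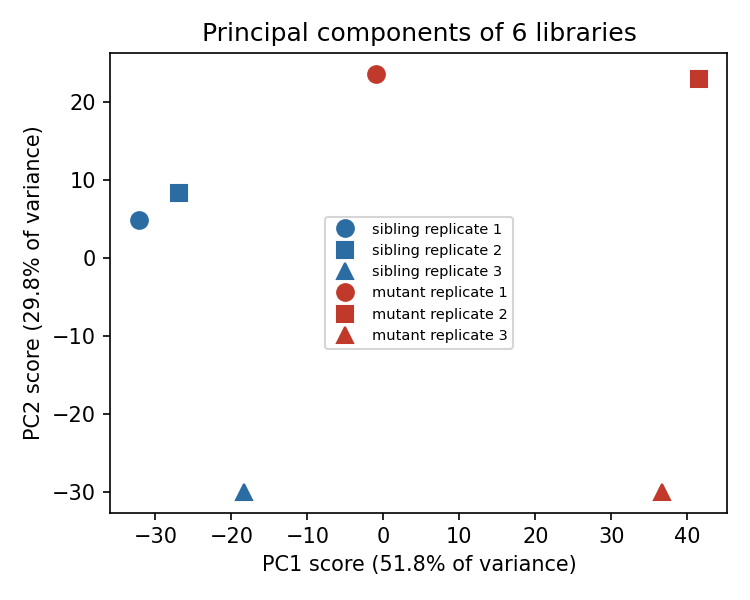
Scores of the 6 libraries on the first 2 principal components (x axis, 51.8% of the variance; y axis, 29.8%; unitless scores of log2 values), siblings in blue and mutants in red, with a marker shape per replicate number. Mutant replicate 1 lies at -0.931 on the first component, between the siblings and the other mutants.

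The comparison asked which transcripts differed between the libraries labelled mutant and their siblings. The targeted gene, *dhx38* (ENSDARG00000100013, chromosome 7), was higher in the 3 mutant libraries, at 57.2, 90.4 and 53.1 normalized CPM, than in the 3 sibling libraries, at 33.8, 33.8 and 27.3. The log2 fold change was 1.03 (SE 0.22), which missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0630) and passed it with the replicate block (adjusted p = 0.00664). With the block and a pseudocount of 0.1 *dhx38* did not pass (limma adjusted p = 0.0789). The labels do not state the mutation, so the transcript level does not check the genotype of these libraries.

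The genes with the smallest p that rose included *snapc4*, *ice1* and *brf2*. *snapc4*, a subunit of the complex that activates snRNA genes, rose from 15.4 ± 0.750 to 163 ± 51.9 normalized CPM (SD, n = 3 per group), and *ice1*, of the little elongation complex that transcribes snRNA genes, rose from 17.3 ± 2.05 to 184 ± 58.0. *brf2*, an RNA polymerase III initiation factor, rose from 8.71 ± 1.70 to 86.1 ± 29.5, and *mettl16*, a methyltransferase of U6 snRNA, from 6.49 ± 1.04 to 59.9 ± 21.6. *rbl2*, of the retinoblastoma family, rose from 9.39 ± 0.821 to 126 ± 58.3.

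The log2 fold changes (limma, Benjamini-Hochberg) were 3.27 for *snapc4* (SE 0.24, adjusted p = 0.00313), 3.28 for *ice1* (SE 0.25, adjusted p = 0.00313), 3.51 for *rbl2* (SE 0.30, adjusted p = 0.00486), 3.12 for *brf2* (SE 0.27, adjusted p = 0.00612) and 2.96 for *mettl16* (SE 0.28, adjusted p = 0.00664). Genes that fell changed less. *phgdh*, the first enzyme of serine synthesis, went from 192 ± 8.59 to 90.8 ± 18.7 normalized CPM (log2 fold change -1.09, limma adjusted p = 0.0317), and the neural transcription factor gene *pou3f2b* from 102 ± 4.32 to 48.3 ± 14.6 (-1.11, limma adjusted p = 0.0469). *pebp1* (-1.37), *poglut1* (-1.45), the histone gene *h2afx* (-1.30), *r3hcc1* (-1.09), *pane1* (-0.94), *wfikkn1* (-0.96), the branched-chain aminotransferase gene *bcat1* (-1.32) and *tmem256* (-0.89) also fell, with limma adjusted p from 0.0198 for *r3hcc1* to 0.0483 for *h2afx*. With a pseudocount of 0.1, *phgdh* (limma adjusted p = 0.0679), *pou3f2b* (0.0939), *pebp1*, *poglut1*, *h2afx* and *bcat1* did not pass, and with that and the block neither did *r3hcc1*, *pane1* and *wfikkn1*.

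In all, 370 of 21769 genes passed the threshold with limma, 308 higher and 62 lower in the mutants. In all 370 the groups did not overlap, as in 27.1% of all genes, against 10% by chance. From this it follows that 370 of the 370 differed in the same direction in each of the 3 same-number pairs. With the replicate block 2986 genes passed, 1491 higher and 1495 lower, among them all 370. With a pseudocount of 0.1, 205 genes passed without the block (190 higher, 15 lower) and 169 with it (156 higher, 13 lower). Nearly all of the 1495 falls called with the block thus did not pass at that pseudocount. Other settings with the block kept many falls: 1873 genes fell with a variance trend and 1780 by the count test. Leaving out sibling replicate 1, 2 or 3 gave 43, 34 or 31 genes and leaving out mutant replicate 2 gave 52, all of them higher in the mutants. Leaving out mutant replicate 3 gave 147, of which 128 were among the 370, and leaving out mutant replicate 1 gave 1731, with 867 higher and 864 lower. *snapc4*, *ice1*, *rbl2* and *brf2* passed in each of these 6 fits, while *phgdh* and *pou3f2b* passed only without mutant replicate 1. In the 4 deeper libraries of replicates 1 and 2 alone, 0 genes passed with limma (4236 at an unadjusted p under 0.05) and 0 with the count test (4264 unadjusted).

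**Figure D2:**
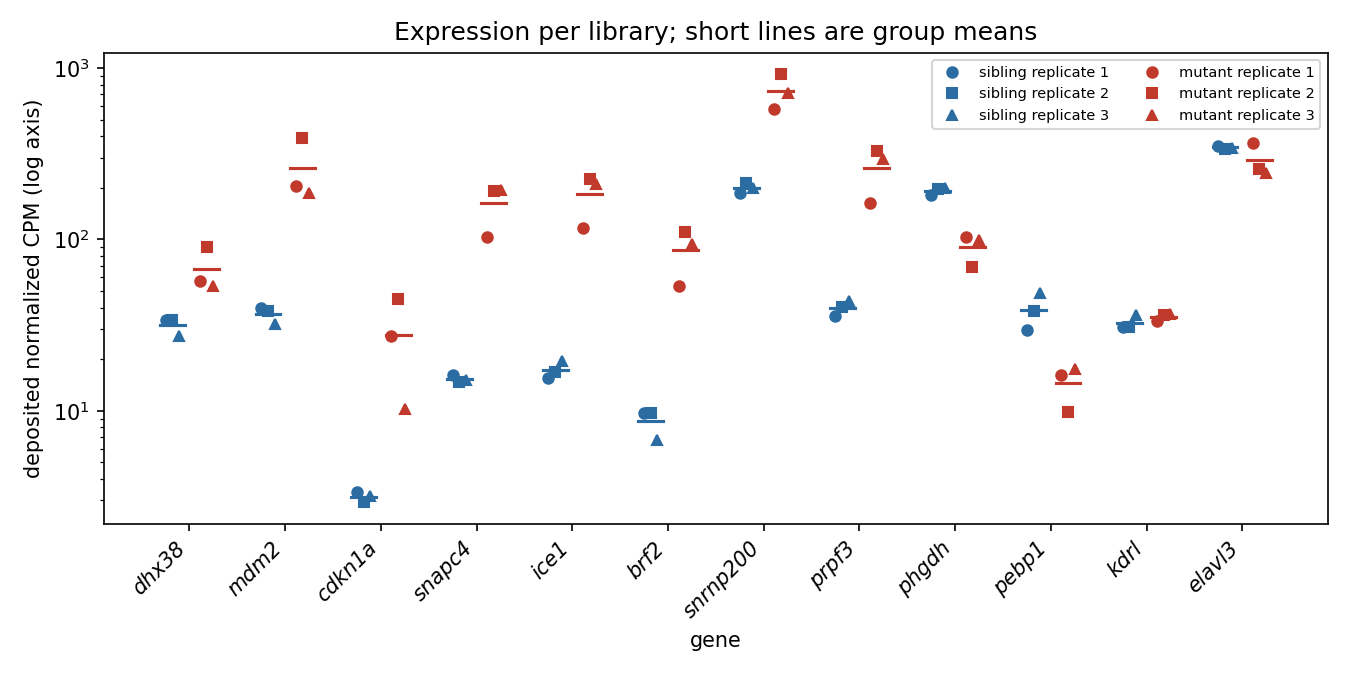
Deposited normalized CPM (y axis, log scale) of 12 named genes (x axis) in each of the 6 libraries, siblings in blue and mutants in red, with a marker per replicate number and short lines for the group means. *snapc4* lies at 103, 191 and 195 in the mutants and at 16.2, 14.8 and 15.1 in the siblings, while *kdrl* and *elavl3* did not pass the test.

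*mdm2*, a ubiquitin ligase gene, rose from 36.5 ± 3.93 to 261 ± 114 normalized CPM (log2 fold change 2.73, limma adjusted p = 0.00664), and *cdkn1a*, the cyclin-dependent kinase inhibitor p21, from 3.15 ± 0.225 to 27.5 ± 17.4 (2.56, limma adjusted p = 0.0352). *cdkn1a* did not pass with a pseudocount of 0.1 (limma adjusted p = 0.0666, and 0.0660 with the block) or in 4 of 6 fits that left out a library (up to 0.137, without sibling replicate 2). The list of apoptosis machinery did not pass by camera, which tests for a shared direction (adjusted p = 0.970). Its 1 called member of 25, *diabloa* (chosen after its values were seen), rose from 7.90 to 18.4 normalized CPM (limma adjusted p = 0.0346). With the replicate block 3 members rose and 4 fell. The fry test for changes in either direction gave the list an adjusted p of 0.0131.

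Spliceosome genes rose as a list. Of 93 measured, 29 rose and 0 fell, and 64 did not pass. In all, 47 rose and 1 fell when adjusted over the list alone, and 47 rose with the replicate block. *prpf3*, a protein of the U4/U6 snRNP, rose from 39.98 ± 4.07 to 261 ± 86.0 normalized CPM (log2 fold change 2.62, limma adjusted p = 0.00664), and *snrnp200*, the helicase that unwinds U4 from U6, from 200.2 ± 13.9 to 737 ± 171 (1.85, limma adjusted p = 0.00664). The list median was 0.50 (camera adjusted p = 1.67e-19; adjusted p = 0.609 with an estimated correlation). SR proteins and hnRNPs, which regulate splice site choice, did not pass as a list (camera adjusted p = 0.970), nor did nonsense-mediated decay and RNA surveillance (camera adjusted p = 0.773). Of their members, 0 of 44 and 0 of 31 were called by limma, 11 and 6 were at an unadjusted p under 0.05, and 0 and 1 by the count test.

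Genes of DNA replication and repair stood lower as lists, with small changes per gene. Of 54 replication genes 0 passed over all genes with limma (19 lower at an unadjusted p under 0.05, 1 lower by the count test), and 8 fell when adjusted over the list alone. With the replicate block 13 fell, among them the ribonucleotide reductase gene *rrm2*, at 572 in siblings and 364 in mutants (chosen after its values were seen). The replication list median was -0.28 (camera adjusted p = 3.73e-06; adjusted p = 0.661 with an estimated correlation). Of 57 DNA damage response and repair genes 1, the Fanconi anaemia gene *fancc* (chosen after its values were seen), fell over all genes (limma adjusted p = 0.04996). The histone gene *h2afx*, which also fell (log2 fold change -1.30, limma adjusted p = 0.0483), was not counted, since the fixed list named it *h2ax*. In all, 18 fell and 1 rose when adjusted over the list alone, and 16 fell with the block (list median -0.21, camera adjusted p = 2.13e-05; adjusted p = 0.609 with an estimated correlation). Of 62 mitosis genes 0 passed with limma (17 lower unadjusted, 0 by the count test, 0 when adjusted over the list alone) and 8 fell with the block. The mitosis list passed (camera adjusted p = 0.00434; adjusted p = 0.698 with an estimated correlation) and did not pass without mutant replicate 1 (adjusted p = 0.163).

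Neural, eye and lens genes stood lower as lists. Of 71 genes of neurons and neural progenitors 0 passed with limma (21 lower unadjusted, 1 by the count test, 0 when adjusted over the list alone) and 21 fell with the replicate block. *gfap*, a marker of glia (chosen after its values were seen), was at 196 in siblings and 98.5 in mutants. The neural list passed (median -0.20, camera adjusted p = 0.000255; adjusted p = 0.661 with an estimated correlation). Of 37 eye and lens genes 0 passed with limma (14 lower unadjusted, 0 by the count test), and 3 fell when adjusted over the list alone. With the block 21 fell (list median -0.72, camera adjusted p = 3.32e-05; adjusted p = 0.661 with an estimated correlation). Within same-number pairs, the eye and lens median was -0.29, -1.11 and -0.94 in pairs 1, 2 and 3, and the neural median -0.23, -0.28 and -0.22. The lens crystallin gene *crybb1* (chosen after its values were seen) was at 470 normalized CPM in these sibling libraries labelled tail or trunk. The head marker *foxg1a* (also chosen then) was at 31.35, 30.91 and 27.41 in sibling replicates 1, 2 and 3. Such values are at odds with tail or trunk tissue alone, and which tissue was taken is not settled here.

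Heat shock, liver and surface genes stood higher. Of 30 heat shock genes 2 rose, *hsf1* by 1.73 and *serpinh1b* by 0.75 on the log2 scale (both chosen after their values were seen). In all, 5 rose when adjusted over the list alone and 11 with the replicate block (camera adjusted p = 5.98e-05; adjusted p = 0.609 with an estimated correlation). Of 43 genes of liver, gut, pancreas and yolk 0 passed with limma (10 higher unadjusted, 0 by the count test, 0 when adjusted over the list alone) and 12 rose with the block. The list passed (median 0.40, camera adjusted p = 5.98e-05; adjusted p = 0.661 with an estimated correlation). Epidermis and ionocytes (camera adjusted p = 0.00346; adjusted p = 0.609 with an estimated correlation), ribosome biogenesis (adjusted p = 0.00239; adjusted p = 0.842 with an estimated correlation) and heart (adjusted p = 0.0138; adjusted p = 0.529 with an estimated correlation) stood higher as lists. Ribosomal proteins stood lower (median -0.20, camera adjusted p = 0.00239; adjusted p = 0.842 with an estimated correlation), with medians of -0.34, -0.15 and -0.08 in same-number pairs 1, 2 and 3. Of these 81 genes 77 had a negative log2 fold change, but 0 passed with limma (2 higher and 0 lower unadjusted). With the replicate block 2 rose and 1 fell. Against the sibling mean, their median was -0.45, -0.31 and 0.20 in mutant replicates 1, 2 and 3. Without mutant replicate 1, ribosomal proteins (camera adjusted p = 0.673) and heart (0.0504) did not pass, nor did ribosome biogenesis without mutant replicate 3 (0.419). The circadian clock list stood higher (camera adjusted p = 0.0330, 0.0537 with the replicate block; adjusted p = 0.661 with an estimated correlation), and the list of unfolded protein and integrated stress responses lower (0.0468, 0.0582 with the block; adjusted p = 0.529 with an estimated correlation). Neither passed without mutant replicate 1 (camera adjusted p = 0.132 and 0.201).

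Blood and vessel genes did not pass as lists. The stem and progenitor genes *runx1* (2.01 ± 1.08 in siblings, 2.93 ± 1.09 in mutants), *myb* (27.0 ± 1.53 and 23.5 ± 1.57), *lmo2* (11.7 ± 1.67 and 9.52 ± 2.72) and the erythroid regulator gene *gata1a* (4.48 ± 1.43 and 5.48 ± 2.54) did not pass (limma adjusted p from 0.464 for *myb* to 0.779 for *gata1a*). The embryonic globin genes *hbae1.1* (2437 ± 1343 and 1508 ± 601) and *hbbe1.1* (671 ± 259 and 419 ± 95.8) overlapped between groups. *lyz* (6.87 ± 5.58 and 3.41 ± 2.95) and *mpx* (46.9 ± 14.8 and 28.9 ± 13.9), of myeloid cells, did not pass (limma adjusted p = 0.487 and 0.254) and fell with the replicate block (limma adjusted p = 0.00850 and 0.0184), but not with the block and a pseudocount of 0.1. Camera adjusted p was 0.847 for haematopoietic stem and progenitor cells, 0.519 for myeloid cells, 0.388 for lymphoid cells and 0.109 for erythroid cells, which passed with the block (0.0413; adjusted p = 0.842 with an estimated correlation).

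The endothelial gene *kdrl* (32.5 ± 3.27 and 35.4 ± 1.75), the neuronal gene *elavl3* (343 ± 5.41 and 289 ± 64.5) and the fast muscle gene *mylpfa* (4642 ± 199 and 4004 ± 432) did not pass. The 1 called gene of 41 in the endothelium list, *stab2* (chosen after its values were seen), rose from 50.2 to 105 normalized CPM (limma adjusted p = 0.0398). Camera adjusted p was 0.539 for endothelium, 0.207 for skeletal muscle, 0.388 for notochord, cartilage and sclerotome, 0.0803 for pigment and neural crest cells, 0.142 for posterior Hox genes and tail bud, and 0.0943 for pronephros. It was 0.0990 for innate immune and interferon response and 0.0678 for hatching gland, which passed with the replicate block (0.0436; adjusted p = 0.661 with an estimated correlation). Of 30 lists 15 passed, 8 higher and 7 lower, and 0 passed with an estimated correlation (1 at an unadjusted p under 0.05), with that and the replicate block (0 unadjusted) or by the directional test of fry (7 unadjusted). Other divisions of the same 6 libraries into 3 and 3 gave up to 14 lists with the preset correlation, and the 3 that part all same-number pairs gave 10, 7 and 12. Each of these divisions splits the genotypes unevenly, so part of the genotype difference can remain in it, and these counts do not measure false calls. Since 0 lists passed with an estimated correlation, a list call at the preset correlation is weak evidence of a genotype difference.

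**Figure D3:**
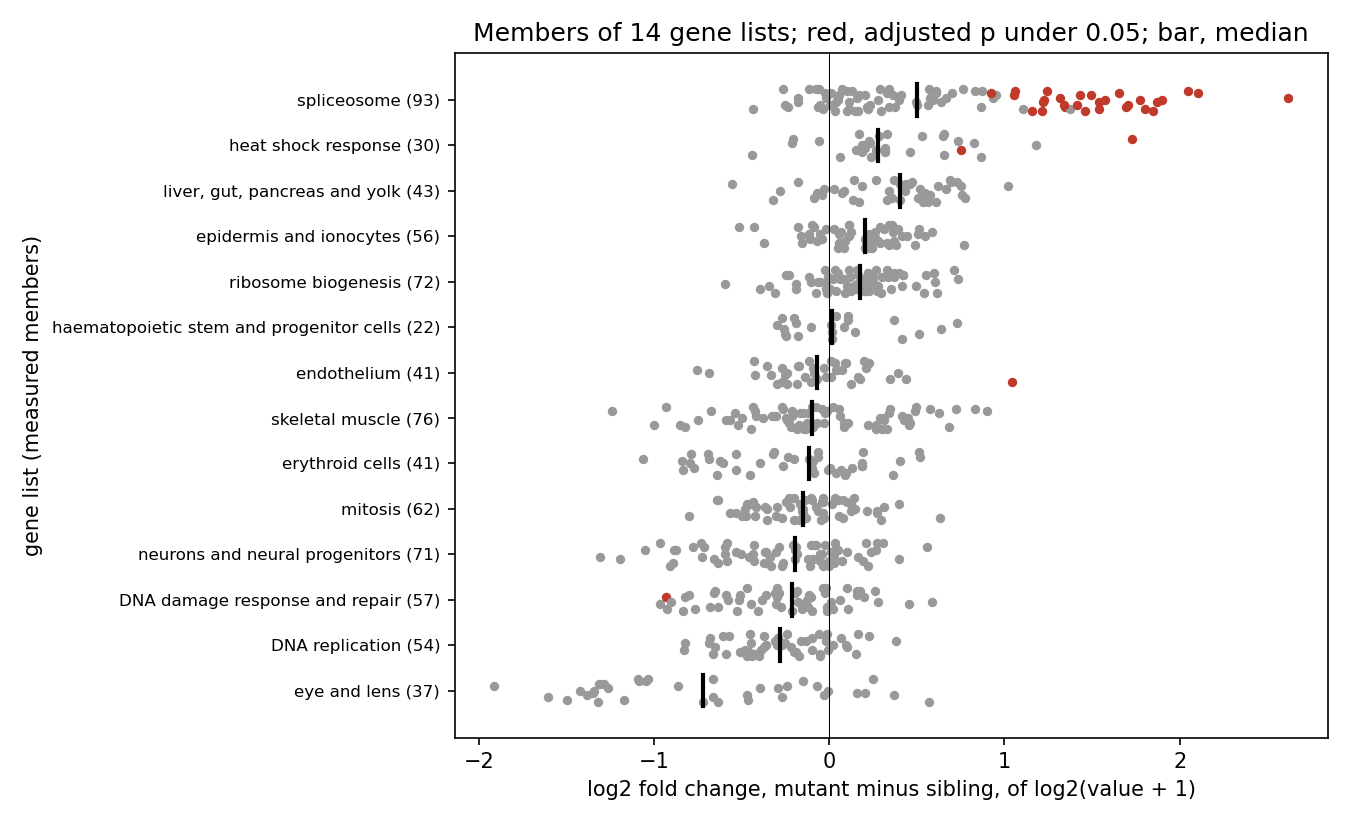
Log2 fold changes (x axis, mutant minus sibling, log2(value + 1)) of the members of 14 fixed gene lists (y axis, number measured in parentheses). Each point is a gene, red where limma adjusted p was under 0.05, and bars are medians. Red points lie mainly in the spliceosome (29), and the eye and lens median is -0.72.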

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

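The variance trend, the pseudocount of 0.1 for gene counts, the count test, its versions with the replicate block and the 4 libraries of replicates 1 and 2 were chosen after seeing the data, and the estimated correlation and fry, named in the fixed design, were entered as alternatives then. The cause of a changed call was not tested unless stated. The 370 genes became 41 at an adjusted p under 0.01, 2986 with the replicate block, 205 with a pseudocount of 0.1, 169 with that pseudocount and the block, 3800 with the block and a variance trend, 3663 with the count test and the block, and 0 in replicates 1 and 2 by limma (4236 at an unadjusted p under 0.05) and 0 by the count test (4264), where fewer libraries were tested. Leaving out single libraries gave 31 to 1731. Counts were within 1.5 times of 370 with a minimum fold change (260), a filter on low values (365), centring (350), a variance trend (482) and the count test (511). Centring lowered the share of higher calls from 83.2% to 76.9%, and the block to 49.9%. *dhx38* passed with the block (adjusted p = 0.00664), the variance trend (0.0419), both (0.000800), the count test (0.0424) and the count test with the block (0.000902), and did not pass with a pseudocount of 0.1 (0.114), also with the block (0.0789), or in replicates 1 and 2 (0.171, and 0.118 by the count test). Leaving out single libraries gave 0.0424 without mutant replicate 1 to 0.197.

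The 15 lists became 7 with a preset correlation of 0.05. They became 0 with an estimated correlation (1 unadjusted), with that and the block (0 unadjusted) and by the directional test of fry (7 unadjusted). The fry test for changes in either direction gave an adjusted p of 0.0103 for spliceosome, 0.0103 for SR proteins and hnRNPs and 0.0336 for replication. For mitosis and repair that test gave 0.00973 each, for neural genes 0.0463, and for eye and lens 0.132, which did not pass. Among lists that did not pass by camera, it gave 0.00973 for nonsense-mediated decay and 0.0131 each for apoptosis and endothelium. Adjusted p with an estimated correlation was 0.609 for spliceosome and repair, 0.661 for replication, neural and eye and lens genes and 0.698 for mitosis; with the block it was 0.661 for all 6. By fry it was 0.0713 for spliceosome, 0.110 for repair, 0.241 for replication, mitosis and neural genes and 0.284 for eye and lens. With a preset correlation of 0.05, mitosis (0.111), neural genes (0.0536), epidermis, ribosome biogenesis and ribosomal proteins (0.107 each), heart (0.0912), circadian clock (0.179) and stress responses (0.244) did not pass. Erythroid genes passed with the log2 fold change as the statistic (0.00588), the replicate block (0.0413) and replicates 1 and 2 only (0.000164), where epidermis (0.0566) and ribosome biogenesis (0.0973) did not pass. With the log2 fold change as the statistic heart (0.0966) and stress responses (0.130) did not pass and innate immune genes did (0.0376). Circadian clock did not pass with ranks (0.0535), nor stress responses with the low-value filter (0.0790) or a pseudocount of 0.1 (0.0617). The block changed the calls of circadian clock, stress response, hatching gland and erythroid genes and of no other list. Among named genes it changed those of *dhx38*, *lyz* and *mpx* alone. The 10 named genes that fell did not pass without sibling replicate 2 or in replicates 1 and 2.

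Directions near 0 reversed without a call: apoptosis with the log2 fold change as the statistic (0.912) and the low-value filter (0.854), myeloid cells with that filter (0.963), *gata1a* in replicates 1 and 2 (0.766, and 0.821 by the count test), and SR proteins and hnRNPs with the log2 fold change (0.912), the block (0.932), the block with an estimated correlation (0.969), fry (0.9998) and replicates 1 and 2 (0.360). Leave-one-out ranges of adjusted p were 0.000213 to 0.163 for mitosis, 5.09e-11 to 0.673 for ribosomal proteins, 3.72e-06 to 0.419 for ribosome biogenesis, 0.00341 to 0.132 for circadian clock, 0.0249 to 0.201 for stress responses, 0.00592 to 0.0504 for heart, 0.000181 to 0.982 for innate immune genes, 0.0406 to 0.334 for pigment cells, 0.0431 to 0.419 for pronephros, 0.0114 to 0.391 for hatching gland, 0.00350 to 0.999 for erythroid cells, 0.534 to 0.985 for stem and progenitor cells, 0.0310 to 0.774 for myeloid cells, 0.00583 to 0.985 for muscle, 0.00350 to 0.756 for notochord, 0.547 to 0.985 for nonsense-mediated decay, 0.00137 to 0.956 for posterior Hox genes, 0.677 to 0.985 for apoptosis, 0.484 to 0.979 for SR proteins and hnRNPs and 0.458 to 0.937 for *gata1a*. DESeq2, a count filter and Benjamini-Yekutieli adjustment were not run, since they were planned for other kinds of file, and intron number was not run for want of an annotation. In simulation, 1.5-fold changes of genes at or above the median expression were not detectable with limma (0 of 50). The simulated libraries carried no effect of replicate number, so this sets no limit for the blocked fit of the data. In that fit *ube2c* (chosen after its values were seen) passed at a log2 fold change of -0.53 (limma adjusted p = 0.0311).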

Other observations

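The subgroups of the spliceosome described here, the lens crystallins and the snoRNA genes were formed after the data were seen, and so were the tests of the neural share, of 5S rRNA and of the shorter table. Within the spliceosome, the proteins of U5 and the tri-snRNP rose most: 11 of 14 passed (limma), with a median log2 fold change of 1.58. The Sm and LSm ring proteins had a median of 1.05 with 5 of 12 higher, the SF3 and U2 proteins 0.61 with 3 of 15, and the Prp19 complex and step factors 0.43 with 7 of 24; 0 fell in any of these. The subgroups come from a list already seen to rise and are not independent evidence.

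Only 1 of 10 splits of the 6 libraries, the real one, called as many as 370 genes; the highest other called 0 (limma; 31 to 3082 at an unadjusted p under 0.05; 0 by the count test). The 3 other splits that part all 3 same-number pairs called 0 genes with the replicate block, against 2986. For lists, 1 of 10 splits gave as many as 15, and the highest other gave 14. With 10 splits the share cannot go below 0.05 for genes or lists, nor can it with the fewer splits that part all pairs. Each other split has both genotypes on both sides, so the genotype difference adds to its residual spread. Few gene calls there were likely from the outset, and 0 calls do not measure false calls. Part of the genotype difference can also remain in such a split, so its list count does not measure false calls either.

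Eye and lens genes stood lower in the mutants, mainly the lens crystallins. Of these, 15 of 15 were lower in each same-number pair, with medians of -0.31, -1.71 and -1.68 in pairs 1, 2 and 3. With the replicate block 14 fell (limma). With that and a pseudocount of 0.1 only 13 of all genes fell, against 1780 by the count test with the block. Less head tissue in the mutant dissections would lower other head markers too. The 27 such markers, some also expressed in trunk tissue, had a median of -0.12 (bootstrap 95% interval -0.29 to -0.02). That was nearer 0 than the bound of -0.36 (0.5 times the eye and lens median). With the replicate block 4 of the 27 fell and 1 rose (limma). An equal loss of all neural tissue predicts equal medians, but the eye and lens median lay below the neural one by a difference of -0.50 (interval -0.97 to -0.15). Both medians went against these explanations for the list as a whole, which the crystallins carry. They did not for the 22 other eye genes, whose median of -0.28 was near the neural -0.20. Nor did they within pair 1 (eye and lens -0.29, head markers -0.17, neural -0.23). The bootstrap intervals, here and below, resample genes of the same 6 libraries and do not measure the spread between libraries. Head markers also expressed in trunk tissue can hide a loss of head tissue, so that explanation is not excluded. A difference in lens content between individual dissections stays open, as does an effect of the genotype on the lens.

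All 24 snoRNA and scaRNA genes had positive log2 fold changes, with a median of 0.89. Of these, 11 rose (limma) and 23 rose with the replicate block. Several share a name, so copies may share reads. Several also lay under the value of 3 reads in siblings (0.0864, 0.0810 and 0.156 in replicates 1, 2 and 3), such as *SNORA70* at 0, 0.05 and 0. The gene filter is not given, so snoRNA genes low in both groups may be missing, which would raise the share of positive values. The snoRNA median was at percentile 100 of 10000 random lists matched on mean expression (central 95%, -0.12 to 0.11), which argues against a shift of all low genes. More small RNA kept in the mutant libraries stays open: 5S rRNA genes had a median of 0.018 (interval -0.10 to 0.22). Of 27 such genes 3 rose and 0 fell (limma), and 6 rose and 1 fell with the replicate block. The bound for that explanation was a median above 0, met only within error, and the demand that the interval exclude 0 was added after the value was seen. Reads from unspliced introns of host genes, a biological candidate in a splicing mutant, were not tested.

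Of the 956 genes in the shorter deposited table, 180 passed with limma and 523 with the replicate block. Among the 433 without a blocked genotype call, 44.1% differed by replicate number, against 2.99% of unlisted genes matched on mean expression, a ratio of 14.8. This is consistent with a criterion that also takes genes that differ by replicate number. No biological explanation was tested.

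A hypothesis was that the wider machinery of snRNA synthesis and assembly rises with *snapc4*, *ice1*, *uspl1* (chosen after its values were seen) and *brf2*. The other 38 members had a median log2 fold change of -0.10 (bootstrap 95% interval -0.18 to 0.02), under the 0.1 fixed beforehand as the bound against it, and 1 of 38 rose and 6 fell with the replicate block (limma). The hypothesis was not borne out for these 38 members. They did not include *mettl16*, which rose, or the Sm and LSm proteins, of which 5 of 12 rose (limma).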
